A study of Mus musculus with 13 samples.

How the data were processed

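RNA from the gastrocnemius muscle of 13 male C57BL/6J mice was measured on 2-colour Agilent 8x60K arrays, 1 array per mouse. Per the labels, 6 mice were wild type and 7 were littermates carrying a UCP1 transgene, the study compared them from the age of 12 weeks, and all were fed a purified low fat diet for 12 weeks. Per the labels' protocols, labelling started from 200 ng of total RNA of each mouse, the Cy5 channel held the individual mouse and the Cy3 channel a pool of samples in equal molar amounts, used as a common reference. The dyes were not swapped, so every ratio was taken as Cy5 over Cy3 and the difference between groups as UCP1 transgenic minus wild type. The labels call the samples individual mice, and each array was counted as 1 replicate.

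The deposited scanner files hold the spot and local background intensity of both channels on a linear scale, per the file headers, as written by Agilent Feature Extraction 10.5.1.1, a version that the submitters' processing notes also name. Per the file headers they also hold flags with other values (well above background, saturated, outlier, control) and the log10 ratio of the processed signals. The deposited value table holds 25583 rows, which were taken as log2 intensities of the authors. Each of its columns had a median of 7.58. Across probes each correlated with the log2 Cy5 signal of its own array at 0.996 to 0.999. The correlation was nearly as high with the log2 Cy3 signal, 0.988 to 0.992, and 0.0675 to 0.147 with the log10 ratio. The table was therefore taken as a Cy5 scale with a common centre in which a higher value is a higher signal. The background correction, the filter and the normalization behind it are not given in the sources used here. The series design text says only that these arrays were normalized together with other samples of a larger series. That table was used as an alternative, matched through the feature number. No per-sample column was left unmapped.

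From the scanner files, the mean signals were corrected with the local background by normexp with an offset of 50, fitted on all spots, and log2 ratios were normalized by loess within each array with limma 3.58.1 in R 4.3.3. Each array held 62976 spots, of which 3671 were controls. Controls and spots with an outlier flag had no weight in the loess and were left out afterwards (278 to 377 flagged spots per array), no spot was saturated, and spots of 1 probe were averaged. Of 55681 probes, 22716 (40.8%) were well above background in Cy5 on at least 6 of the 13 arrays and were kept. The brightest kept probe stood for each gene name of the files, which gave 17257 genes, of which 4035 had several kept probes. In 24 genes the probes passed the threshold in opposite directions. Gene names are those of the array design. Of the 17257 genes, 11860 were matched by accession, 745 by symbol and 119 by an older symbol to a table of the assembly GRCm38.p6, which was used for names only, and 4533 kept the file's name without a match. Coordinates are those of the probes in mm9 (NCBI37), per the file headers.

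The groups were compared with lmFit and eBayes of limma, two-sided, on all 13 arrays without a covariate, with Benjamini-Hochberg adjustment over the 17257 genes and a threshold of 0.05 on the adjusted p. Errors of differences are standard errors of the limma fit, and errors of group means are standard deviations between mice. Where a probe was not well above background on any array of 1 group, the change is given as a lower bound. It sets the mean Cy5 signal of the brighter group, after loess and Aquantile scaling, against the mean over the arrays of the dimmer group of the higher of the probe's own signal and the lowest signal of any probe well above background. Without a dye swap this bound is open to dye bias. For 25 lists of genes and 11 lists of markers of other cell types the test was camera with a preset correlation of 0.01, adjusted within each of these families, on lists with at least 4 measured members and on genes without a missing value (124 genes had one). Camera with an estimated correlation and fry were run beside it. The gene lists were integrated stress response regulators, enzymes of serine, glycine and one-carbon metabolism, other enzymes of amino acid synthesis and interconversion, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, secreted factors of muscle, mitochondrial chaperones and proteases, endoplasmic reticulum stress genes, respiratory complex I, respiratory complexes II to IV, ATP synthase, citric acid cycle, fatty acid oxidation, glycolysis and glycogen, slow-fibre and fast-fibre contractile genes, regulators of mitochondrial biogenesis, antioxidant genes, atrophy and autophagy genes, denervation and regeneration genes, fatty acid and triglyceride synthesis, clock genes, immediate early genes, cytosolic heat shock genes, and insulin and growth signalling. The cell type lists covered white and brown adipocytes, endothelial cells, smooth muscle and pericytes, fibroblasts, macrophages, lymphocytes, red blood cells, Schwann cells and nerve, satellite cells and neutrophils. Of 564 list members, 526 were measured.

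Genes were named by a rule with 5 parts. The first is Ucp1 and Fgf21. The second is the 12 genes with the largest change in each direction that passed the threshold, had the same direction within each slide, did not overlap between the groups, were measured in both groups and had a gene symbol. The third is up to 6 genes in each direction with the largest lower bound. The fourth is up to 4 members of each gene list with the smallest p past the threshold, and the fifth is up to 3 markers of each cell type. The design, this rule, the lists and most alternatives were fixed before the data were examined.

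The 13 arrays lay on 4 slides, as their barcodes show, and each slide held both groups, so differences were also computed within each slide and with the slide as a block. Scan dates were not used here. The alternatives were no background correction, an offset of 16, Agilent's own log ratio, centring on the median without loess, Aquantile scaling after loess, Cy5 alone with quantile normalization, the authors' value table, no filter on dim probes, a filter on all 13 arrays, every probe on its own, the mean over a gene's probes, the slide as a fixed or random block, a replicate block, eBayes with trend and robust, array weights, a log2 difference of at least 1, an adjusted p under 0.01, and leaving out each array in turn. Keeping spots with an outlier flag and a covariate of the mean of 4 adipocyte markers were added after the data had been seen.

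The fit was tested on simulated data with the spread of the 17133 complete genes of this comparison and 50 changed genes per size. It recovered 22% of genes changed by 0.25 on the log2 scale, 86% of those changed by 0.5, and 100% of those changed by 1 and by 2, and 4 of its 158 calls were unchanged genes. A simulated list of 20 genes shifted by 0.5 was called and none of 24 unchanged lists was (0 of 24), with genes simulated as independent of each other. The number of arrays limits the precision of every value.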

Results

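The study compared gene expression in the gastrocnemius, a calf muscle, between mice that overexpress UCP1 in skeletal muscle and their wild-type littermates. UCP1 is the uncoupling protein of brown fat mitochondria, which lets protons return to the matrix without the synthesis of ATP. The stated interest was in a shortage of amino acids in this muscle and in signalling through FGF21, a circulating metabolic hormone. Each of 6 wild-type and 7 transgenic mice was measured against the same reference pool. Between 20643 and 24036 of 55681 probes per array (37.1% to 43.2%) were well above background in the mouse channel. Their number was 21916 ± 1140 (SD, n = 6) in wild-type and 22835 ± 1250 (SD, n = 7) in transgenic samples. An exact permutation test of the group labels did not call this difference (two-sided p = 0.188). The median spot signal of that channel was 40.4 to 50.8 units over a background of 29 to 33 units. Across genes, the log2 ratios of arrays of 1 group correlated with each other at 0.52 to 0.77 in wild type and 0.38 to 0.73 in transgenic samples. Arrays of different groups correlated at -0.25 to 0.15. These ratios to the reference pool were not centred per gene. Genes are not independent replicates, so no p-value goes with these correlations.

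Ucp1 was higher in the transgenic samples by 3.23 ± 0.50 on the log2 scale (SE), a 9.41-fold difference, with an adjusted p of 5.6e-05 in the limma test with Benjamini-Hochberg adjustment. Without the array labelled wild type 4 the difference of Ucp1 was 3.91 ± 0.20 (SE, adjusted p = 2.7e-11). Its log2 ratio to the reference pool was 0.32 ± 0.38 (SD, n = 7) in the transgenic samples, from -0.20 to 0.85. It was -3.58 ± 0.50 (SD, n = 5) in the wild-type samples other than array 4, none of which exceeded -2.82. The array labelled wild type 4 read 0.45 for Ucp1, within the range of the transgenic samples, which goes against its label, and 3 of the 7 transgenic arrays lay above all 6 arrays labelled wild type. The probe lies on chromosome 8 from 85821788 to 85821847 and was the only probe for this gene. Within slides the difference was 4.12, 3.87, -0.13 and 3.73, where the third value is from the slide of the array labelled wild type 4. With Agilent's own log ratio it was 3.99. It was 2.99 with the slide as a fixed block and 3.14 with the slide as a random block. With a covariate of adipocyte markers the difference of Ucp1 was 1.32 and no longer passed the threshold (adjusted p = 0.333). Among the wild-type arrays that covariate was highest on the array labelled wild type 4 (-0.20), where Ucp1 was highest too. This fit therefore does not show that fat content explains the difference of Ucp1.

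Fgf21 was 16.2-fold higher in the transgenic samples, a difference of 4.02 ± 0.17 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 8.4e-13). Its log2 ratio was 0.62 ± 0.47 (SD, n = 7) in transgenic and -3.39 ± 0.22 (SD, n = 6) in wild-type samples. All 7 transgenic arrays lay above all 6 arrays labelled wild type, including array 4, which read -3.60. The probe lies on chromosome 7 from 52869305 to 52869364. The difference was 3.63 to 4.30 within the 4 slides, 4.06 with the slide as a fixed block and 4.88 with Agilent's own log ratio.

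**Figure D1:**
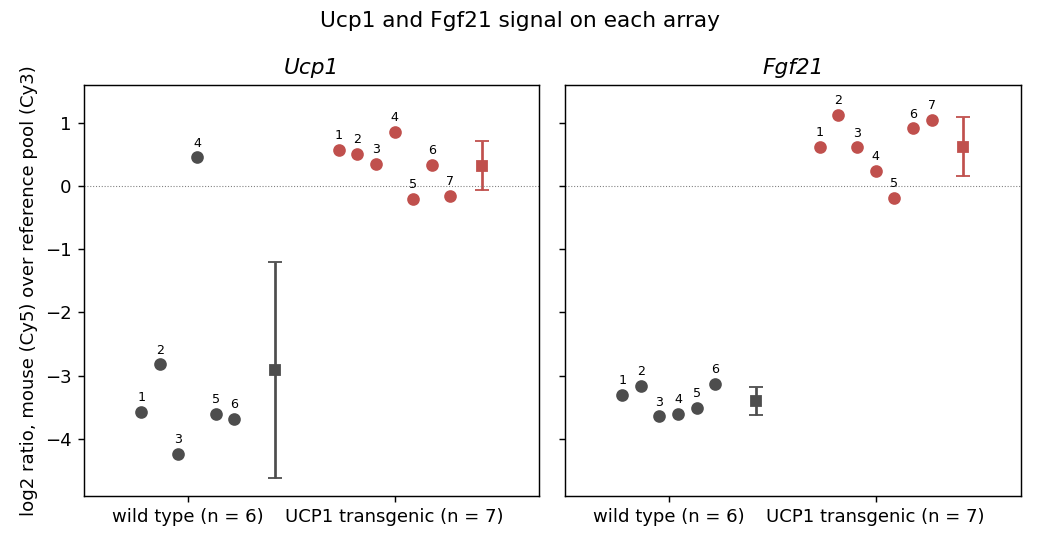
Log2 ratio of the mouse sample over the reference pool for Ucp1 (left) and Fgf21 (right) on each array, with replicate numbers at the points and squares with bars for the mean ± SD of 6 wild-type and 7 UCP1 transgenic arrays. Fgf21 separates the groups, while for Ucp1 the array labelled wild type 4 reads 0.45, among the transgenic arrays.

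Of 17257 genes, 5695 (33.0%) passed the threshold between the groups in the limma test, 2910 higher and 2785 lower in the transgenic samples. Most differences were small in this scaling, and 4280 of the 5695 (75.2%) were under 0.5 on the log2 scale. The offset of 50 draws the log ratios of dim spots toward 0, so sizes depend on it. With Agilent's own log ratio the median of serine, glycine and one-carbon enzymes was 0.76 against 0.47. That of fast-fibre genes was smaller in size, -0.41 against -0.65. At a difference of at least 1, 137 genes were higher and 148 lower. In 2543 genes the 7 and the 6 arrays did not overlap, where chance gives 20.1 (0.117% of genes), and 2536 of these passed the threshold. Of the 5695 genes, 5321 (93.4%) had the same direction within each of the 4 slides, and 6168 genes passed with the slide as a fixed block. The genes were called on these same arrays, so the agreement within slides is partly built in and is no separate test. Some slides also held only a single array of a group. Without the array labelled wild type 4, 5631 genes passed. The number was 1303 when arrays were centred on the median without loess, which shifted the median of all genes to 0.14, and the share of higher genes was then 79.7% against 51.1%. With the adipocyte covariate 2482 genes passed.

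Trib3, a pseudokinase induced by the integrated stress response, was 23.9-fold higher (4.58 ± 0.12 on the log2 scale, adjusted p = 1.2e-15). Psat1, an enzyme of serine synthesis, was 21.2-fold higher (4.41 ± 0.08) on its brightest probe, and less so on its other probe. Asns, which makes asparagine, was 17.7-fold higher (4.15 ± 0.08). Mthfd2, a mitochondrial enzyme of the folate cycle, and Gdf15, a secreted stress hormone, were both 12.3-fold higher (3.63 ± 0.12 each). All 7 transgenic arrays lay above all 6 arrays labelled wild type for each of these 5 genes. With Agilent's own log ratio the differences were 5.28 for Gdf15, 4.43 for Mthfd2, 5.08 for Psat1 and 4.79 for Asns on the log2 scale, and with the mean over its probes that of Psat1 was 2.95. The integrated stress response slows translation and raises the transcription factor ATF4 and its targets. Of 15 measured regulators of this response, 11 rose and 2 fell, also when adjusted over the list alone, with a median of 0.87, and 11 rose and 0 fell under median centring without loess. Besides Trib3, the transcription factor Atf5 rose by 2.61, the translation inhibitor Eif4ebp1 by 1.98 and Cebpg, a partner of ATF4, by 1.06. The members that fell were Ddit4 (-1.46), an inhibitor of mTORC1, and Vldlr (-0.86), a lipoprotein receptor. The list lay above other genes (camera, adjusted p = 1.2e-08), with an adjusted p = 0.060 with an estimated correlation.

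Of 16 measured enzymes of serine, glycine and one-carbon metabolism, 10 rose and 1 fell (11 and 1 adjusted over the list alone, 8 and 0 under median centring without loess), with a median of 0.47. Phgdh, the first enzyme of serine synthesis, rose by 2.02, beside Psat1 and Mthfd2, while Gcat, which breaks down threonine, fell by 0.21. No member fell (0) without wild-type array 2, 3, 4 or 5 or transgenic array 1, 3, 4 or 5. Of 17 other enzymes of amino acid synthesis and interconversion, 9 rose and 2 fell (9 and 3 adjusted over the list alone, 7 and 0 under median centring without loess), with a median of 0.26. The proline synthesis enzymes Pycr1 and Aldh18a1 rose by 1.82 and 1.78, whereas the ornithine enzyme Oat fell by 0.26. By Agilent's own log ratio Phgdh was at 2.94, Pycr1 at 3.11 and Aldh18a1 at 3.43. Both lists passed the set test (camera, adjusted p = 1.3e-07 and 9.3e-04) and each had an adjusted p = 0.031 with an estimated correlation. Of 18 amino acid transporters, 7 rose and 2 fell, also when adjusted over the list alone, with a median of 0.16. Slc3a2, the shared heavy chain of several exchangers, rose by 1.63 and the glycine transporter Slc6a9 by 1.34. Slc7a5, a light chain for large neutral amino acids, rose by 1.84 on its brightest probe but read -0.17 on its other probe, and was at 2.91 with Agilent's own log ratio. The transporters Slc38a4 and Slc7a8 were lower, by -1.61 and -0.52. The list passed the set test (adjusted p = 0.0022, and adjusted p = 0.136 with an estimated correlation).

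Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 14 rose, 0 fell and 6 did not pass, with a median of 0.50. The counts were 15 higher and 0 lower adjusted over the list alone, and 11 and 0 under median centring without loess. Gars, the glycine enzyme, rose by 1.35, Sars by 1.11 and Iars by 1.03. The set test gave an adjusted p = 1.2e-08, and an adjusted p = 0.099 with an estimated correlation. Within the 4 slides the medians were 0.95 to 1.15 for the stress regulators, 0.36 to 0.56 for serine, glycine and one-carbon enzymes, 0.17 to 0.45 for the other amino acid enzymes, 0.05 to 0.37 for the transporters and 0.38 to 0.71 for the synthetases. The direction of these 5 lists was the same under every scaling tried. In the same samples the median of white adipocyte markers was higher by 0.86. Ddit4, Vldlr, Gcat, Oat and Slc7a8 lie outside the rule for named genes and were chosen after their values were seen.

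**Figure D2:**
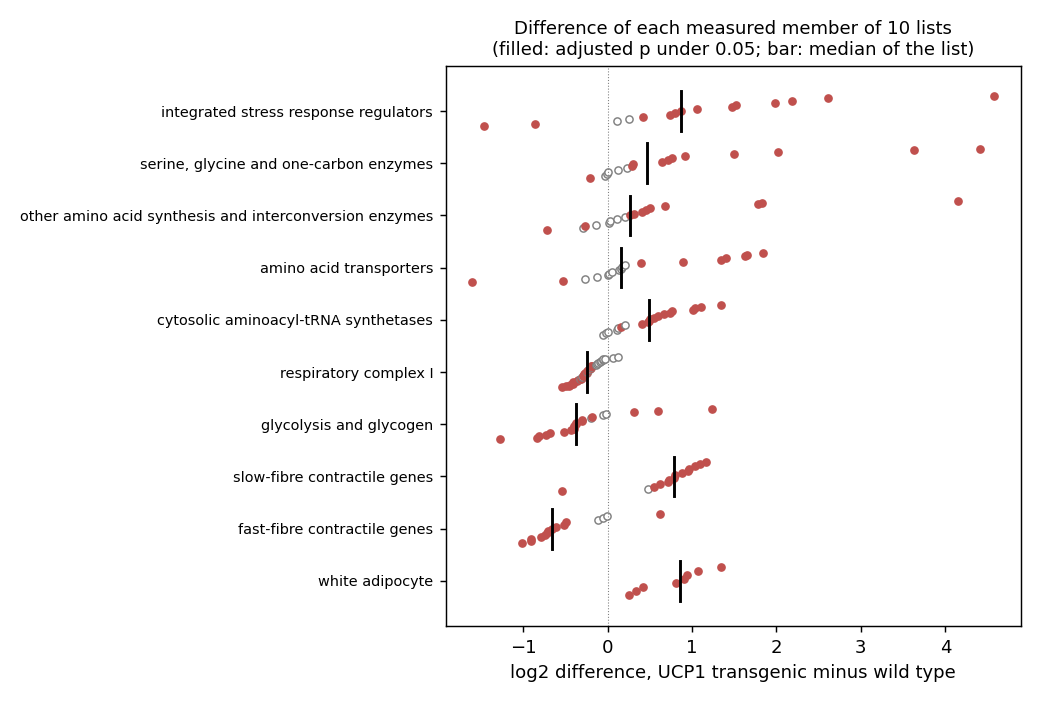
Log2 difference between UCP1 transgenic and wild-type samples for each measured member of 10 lists, filled where the adjusted p of the limma test was under 0.05, with a black bar at the median of each list. Stress response, amino acid and synthetase lists lie above 0 with medians of 0.16 to 0.87, and respiratory complex I, glycolysis and fast-fibre genes lie below 0 with loess, although with median centring without loess complex I has a median of 0.11, which is -0.03 relative to all genes.

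Genes outside these lists changed as well. Ankrd1, a titin-binding protein raised by stretch or denervation, was 10.2-fold higher (3.34 ± 0.14). Soat2, which esterifies cholesterol, rose by 3.17, Cdsn, an adhesion protein of skin, by 2.98, Arhgap33 by 2.89 and Gadd45a, a growth arrest gene, by 2.65. With Agilent's own log ratio Soat2 was at 4.24, Cdsn at 4.56 and Arhgap33 at 4.34. The strongest decrease was that of Amd2, an adenosylmethionine decarboxylase of polyamine synthesis, at -3.91 ± 0.15 (adjusted p = 2.2e-13) and -3.55 and -2.54 on its other probes. Zmynd17, now named Mss51 and known from muscle mitochondria, was at -3.29, and Smox, the spermine oxidase, at -2.72. Dkk3, a secreted protein of the Dickkopf family, was at -2.57 and the calcium channel Itpr1 at -2.42. Further decreases were -2.34 for Hmga2-ps1 and for Odf3l2, -2.19 for Gadd45g, -2.18 for Cd24a, -2.14 for the mitotic kinase Aurka, -2.09 for Golm1 and -2.02 for Smtnl2. Each of these genes from Ankrd1 to Smtnl2 passed the limma threshold with no overlap between the groups. Some probes were not well above background on any wild-type array, and these genes were higher by at least 3.44-fold for the bile acid oxidase Acox2, 2.96-fold for the arginine transporter Slc7a3, 2.78-fold for Fut1, 2.41-fold for Kcne1l and 2.33-fold for Akr1b7 (largest adjusted p = 2.6e-06). For Kcne1l a second probe read 0.15 on the log2 scale. Those not well above background on any transgenic array were lower by at least 3.04-fold for the protease Htra4, 2.01-fold for Igfn1, 1.80-fold for Lrtm2, 1.46-fold for Tmem132b and 1.43-fold for Ly6g6e (largest adjusted p = 2.8e-04). Renin Ren1 rose and Snph fell by the same test (adjusted p = 1.9e-10 and 5.7e-07), but no bound is given for them, since that from the Cy5 channel exceeded the difference of their ratios.

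Among secreted factors of muscle, 4 of 17 rose and 3 fell, also when adjusted over the list alone, with a median of 0.10. Besides Fgf21 and Gdf15, the peptide Ostn rose by 1.42 and the chemokine Cxcl10 by 0.96 (2.76 with Agilent's own log ratio). Myostatin Mstn (-0.46), Igf1 (-0.28) and Fndc5 (-0.20), chosen after their values were seen, were lower, and under median centring without loess 0 members were lower. The number lower was 1 in the authors' value table and 1 without wild-type array 1 or 2 or transgenic array 1, 5 or 7. As a list they had an adjusted p = 0.042, within-slide medians of -0.00 to 0.19, and an adjusted p = 0.164 with an estimated correlation. The call ended without wild-type array 3 (0.053) or 4 (0.064) and without transgenic array 1 (0.053) or 3 (0.062), and it ended under other settings with adjusted p up to 0.354. Of 15 mitochondrial chaperones and proteases, 8 rose and 1 fell, also when adjusted over the list alone, with a median of 0.20, but 2 rose and 0 fell under median centring without loess. Hspa9, the mitochondrial HSP70, rose by 1.14, its partner Dnaja3 by 0.49, and Trap1 (0.40) and the protease Lonp1 (0.35) rose too, although with no call in that scaling, whereas Spg7, chosen after its value was seen, fell by 0.33. The adjusted p of the list was 0.0051, with an adjusted p = 0.164 with an estimated correlation, and the medians within slides were 0.10 to 0.31. Of 18 endoplasmic reticulum stress genes, 6 rose and 0 fell (3 and 0 under median centring without loess), also when adjusted over the list alone, with a median of 0.15. They included Herpud1 (0.75), which acts in protein degradation, and the co-chaperone Dnajb9 (0.65). Their list had an adjusted p = 0.022, and an adjusted p = 0.326 with an estimated correlation. That call ended without the array labelled wild type 4 (0.085) and with a filter on all 13 arrays (0.057), and the medians within slides were 0.02 to 0.50.

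**Figure D3:**
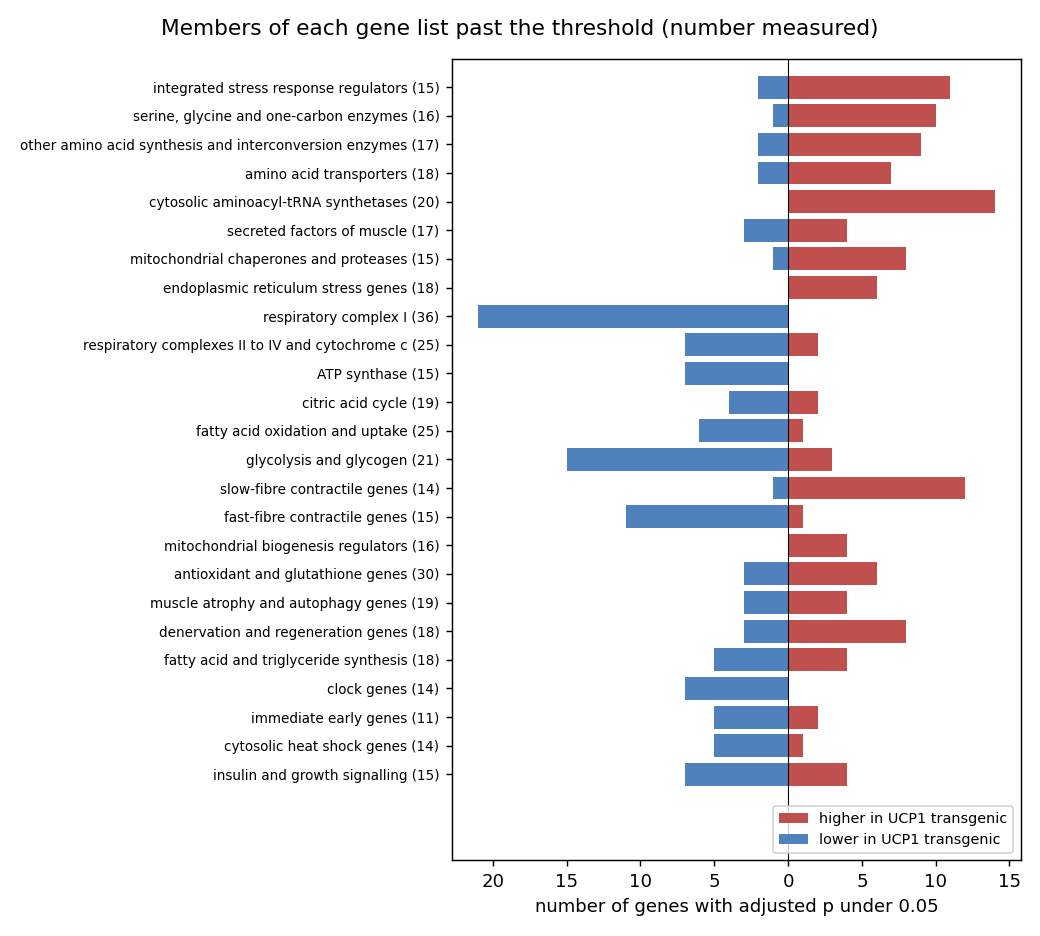
Number of members of each of 25 gene lists that were higher (right, red) or lower (left, blue) in UCP1 transgenic than in wild-type samples at an adjusted p under 0.05 in the limma test, with the number measured in brackets. Cytosolic aminoacyl-tRNA synthetases show 14 higher and 0 lower, and respiratory complex I shows 0 higher and 21 lower, of which 0 remain with median centring without loess.

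Of 36 subunits of respiratory complex I, the entry point of NADH, 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.24, or 0.11 under median centring without loess, which is -0.03 relative to all genes. Of complex I 8 members were lower in the authors' value table. Ndufc1 was at -0.45 and Ndufa13 at -0.41, although in Cy5 alone Ndufa13 no longer passed (-0.14). Complex I as a list had an adjusted p = 1.6e-06, an adjusted p = 0.107 with an estimated correlation, and 0.206 under median centring. Of 25 members of respiratory complexes II to IV and cytochrome c, 7 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.18, or 0.14 under median centring (-0.0035 relative to all genes), where 0 fell and 1 rose, and 4 fell and 3 rose in the authors' value table. Cox8b (-0.61) and Cox7a1 (-0.62) of cytochrome oxidase fell, without a call under median centring, while Cox6a2 (0.97) and, chosen after its value was seen, Cox7a2 (0.23) rose. Without wild-type array 1, 3 or 6 or transgenic array 1 the number higher was 1. That list did not pass (adjusted p = 0.133), but it passed without wild-type array 5 (0.041) or transgenic array 6 (0.045). The same test also called it in Cy5 alone (0.036), without the filter on dim probes (0.041), with every probe on its own (0.014) and with outlier spots kept (0.013). No call came with Agilent's own log ratio (0.085), under median centring (0.695) or in the authors' value table (0.843). Of 15 ATP synthase subunits, 7 fell and 0 rose, also when adjusted over the list alone, with a median of -0.19 that turned to 0.19 under median centring without loess (0.04 relative to all genes). Its member Atp5l was at -0.52, and 2 members were lower in the authors' value table. The set test on 10 of them gave an adjusted p = 0.015, an adjusted p = 0.164 with an estimated correlation, 0.837 under median centring and 0.776 in the authors' value table.

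In the citric acid cycle 2 of 19 genes rose and 4 fell (2 and 0 under median centring, 2 and 2 in the authors' value table), also when adjusted over the list alone, among them Idh2 (0.58), Suclg2 (0.44) and Mdh2 (-0.39, and -0.14 without a call in Cy5 alone). Its median of -0.09 turned to 0.21 under median centring (0.07 relative to all genes), and the list did not pass (adjusted p = 0.408). Of 25 genes of fatty acid oxidation and uptake, 1 rose and 6 fell (1 and 3 adjusted over the list alone), and the median of -0.03 turned to 0.25 under median centring (0.11 relative to all genes) and to 0.03 in the authors' value table, with 0 members lower and 1 lower. Of these fatty acid oxidation and uptake genes 3 fell without wild-type array 1, 2 or 4 or transgenic array 4, and 2 rose without wild-type array 2, with the slide as a fixed block or in the authors' value table. The median of the fatty acid oxidation and uptake list was above 0 without wild-type array 2 (0.02), without transgenic array 2 (0.0060) or 4 (0.0035) and with the slide as a fixed block (0.01). The fatty acid carrier Cd36 rose by 0.47 and the uncoupling protein Ucp3 was at -0.84, and the list did not pass (adjusted p = 0.408). Glycolysis and glycogen genes had 15 of 21 members lower and 3 higher (16 and 3 adjusted over the list alone, 8 and 3 in the authors' value table), with a median of -0.38. Phosphoglucomutase Pgm2, now named Pgm1, was at -1.27, the phosphorylase kinase subunit Phkg1 at -0.83 and Pgam2 at -0.81, while the glycogen branching enzyme Gbe1 rose by 1.24. Also higher were Ldhb (0.60) and Hk1 (0.31), chosen after their values were seen. For the list camera gave an adjusted p = 1.9e-04 and an adjusted p = 0.099 with an estimated correlation. Under median centring without loess the glycolysis and glycogen list had 1 member lower, a median of -0.02 (-0.16 relative to all genes) and an adjusted p of 0.142. Within the 4 slides the medians were -0.31 to -0.20 for complex I, -0.25 to -0.09 for complexes II to IV, -0.34 to -0.14 for ATP synthase and -0.51 to -0.26 for glycolysis. Regulators of mitochondrial biogenesis had 4 of 16 members higher and 0 lower (3 and 0 adjusted over the list alone, 1 and 0 under median centring without loess, 2 and 0 in Cy5 alone), among them the nuclear receptor Esrrg (1.55) and Tfb1m (0.43), with a median of 0.09, and did not pass (adjusted p = 0.131). That list passed the set test without the filter on dim probes (0.034), with every probe on its own (0.039) and under median centring (0.045). It also passed with the adipocyte covariate (0.020) and by fry (5.2e-05). It did not pass with Agilent's own log ratio (0.126), in Cy5 alone (0.107) or in the authors' value table (0.072).

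With loess, most measured contractile genes of slow fibres rose and most of those of fast fibres fell. Of 14 slow-fibre genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone, 12 and 0 under median centring without loess), with a median of 0.79. The slow myosin heavy chain Myh7 rose by 1.17, slow troponin Tnnt1 and the myosin Myh7b by 0.96 and Actn2 by 0.80. Myoglobin Mb, chosen after its value was seen, was the exception at -0.54. Of 15 fast-fibre genes, 11 fell and 1 rose, also when adjusted over the list alone, with a median of -0.65. Myl1 was at -1.01, the calcium buffer Pvalb at -0.91, Casq1 at -0.90 and Tnnc2 at -0.79, whereas the fast myosin Myh1, chosen after its value was seen, rose by 0.62. The set tests gave adjusted p = 1.2e-06 for slow and 8.3e-08 for fast fibres, and with an estimated correlation an adjusted p = 0.177 and an adjusted p = 0.099. For fast fibres 0 members were lower under median centring without loess (median -0.28, which is -0.42 relative to all genes). In Cy5 alone 5 were lower (median -0.10), where Myl1 was at -0.32 and Pvalb at -0.25 and Tnnc2 (-0.12) no longer passed. The fast-fibre list still passed the set test under median centring (camera, adjusted p = 6.8e-05) and in Cy5 alone (0.012). By the mean of the slow-fibre genes wild-type array 1, at 0.03, lay among the transgenic arrays (-0.07 to 0.45), while the other wild-type arrays lay at -0.99 to -0.55. Within slides the medians were 0.17 to 1.12 for slow-fibre and -0.71 to -0.29 for fast-fibre genes. Among 18 denervation and regeneration genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone, 7 and 1 under median centring without loess, 8 and 1 in Cy5 alone), with a median of 0.28. Besides Ankrd1 and Gadd45a, the myogenic factor Myog rose by 1.39, and Dkk3 fell. This list had an adjusted p = 0.015, an adjusted p = 0.180 with an estimated correlation, and medians of 0.04 to 0.29 within slides.

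Of 14 clock genes, 7 fell and 0 rose, also when adjusted over the list alone, with a median of -0.24. Under median centring 2 fell and the median was -0.01, which is -0.15 relative to all genes. The clock list still passed the set test in that scaling (camera, adjusted p = 0.0030). Without transgenic array 1, 1 clock gene rose. Hlf was at -0.95, Per1 at -0.72 and Bhlhe41 at -0.51. Within slides the medians were -0.42 to -0.07. Clock genes passed with an adjusted p = 0.0074, an adjusted p = 0.164 with an estimated correlation, and 0.081 with the adipocyte covariate. Antioxidant and glutathione genes had 6 of 30 members higher and 3 lower (10 and 3 adjusted over the list alone, 2 and 0 under median centring without loess, 9 and 5 with Agilent's own log ratio), among them Gpx3 (1.16), Gstm2 (1.07) and Prdx5 (-0.40, without a call under median centring), with a median of 0.18 and an adjusted p of 0.145. That list passed the set test in the authors' value table (0.015), under median centring (0.025) and without the filter on dim probes (0.041). It also passed with every probe on its own (0.044) and by fry (2.7e-05), but not in Cy5 alone (0.107) or with Agilent's own log ratio (0.288). Atrophy and autophagy genes had 4 of 19 higher and 3 lower (4 and 0 under median centring), also when adjusted over the list alone, with a median of 0.07 and an adjusted p of 0.429. The lysosomal protease Ctsl rose by 2.33 and Map1lc3a by 0.89, and the ubiquitin ligase Fbxo32 was at -0.78. In fatty acid and triglyceride synthesis 4 of 18 rose and 5 fell (6 and 5 adjusted over the list alone, 3 and 0 under median centring), with Me1 at -0.97 and Scd1 at 1.16. Scd1, which adipocytes also express, was at 0.14 and no longer passed with the adipocyte covariate, and the median of white adipocyte markers was higher by 0.86 in the same samples. The median of that list was 0.11 and camera gave no call (adjusted p = 0.911), while fry put the list on the lower side (adjusted p = 0.724). Immediate early genes had 2 of 11 higher, including Egr1 at 2.28, and 5 lower, including Nr4a1 at -0.70, also when adjusted over the list alone, but under median centring 2 were higher and 0 lower and Nr4a1 had no call. Their median was -0.25, their mean -0.02 and their adjusted p 0.408. Cytosolic heat shock genes had 1 of 14 higher, Hspb7 (0.90), and 5 lower, including Hspa1a (-1.60), also when adjusted over the list alone. The number of lower heat shock genes was 2 without wild-type array 5 or 6, 3 without wild-type array 1 or transgenic array 3, 5, 6 or 7, and 7 without the array labelled wild type 4. It was 1 under median centring and 3 with Agilent's own log ratio, in Cy5 alone and in the authors' value table. Their median of -0.12 turned to 0.17 under median centring (0.03 relative to all genes), and the set test gave an adjusted p = 0.242, or 0.045 without the array labelled wild type 4. Insulin and growth signalling had 4 of 15 higher, such as Grb10 (0.73), and 7 lower, such as Rragd (-0.95), also when adjusted over the list alone, or 2 higher and 1 lower under median centring, with a median of -0.00 that was 0.12 under median centring (-0.02 relative to all genes) and an adjusted p of 0.633.

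Markers of white adipocytes were higher in the transgenic samples, with 8 of 8 past the threshold, also when adjusted over the list alone, and a median of 0.86. The number higher was 5 without wild-type array 1 or 5, 5 under median centring without loess and 6 in Cy5 alone. The gluconeogenic enzyme Pck1 rose by 1.34, complement factor Cfd by 1.07 and the hormone Adipoq by 0.81. White adipocyte markers as a list had an adjusted p = 5.8e-04, and an adjusted p = 0.605 with an estimated correlation. Within slides the median was 1.01, 1.19, -0.04 and 0.50, where the third value is from the slide of the array labelled wild type 4. With the adipocyte covariate the red blood cell genes Alas2 and Hba-a1 read -0.057 and -0.16. The calls of Pck1, Alas2, Hba-a1, Col1a1, Col1a2, Cspg4, Cd4, S100b and Chodl ended with it, as did those of Cox8b, Suclg2, Mdh2, Cd36, Ucp3, Tfb1m, Gstm2, Fbxo32, Scd1, Per1, Hspa1a, Grb10 and Ly6g6e. For Adipoq and Cfd, which are part of the covariate, it says nothing. No other cell type list passed camera, whereas fry also called the lists of red blood cells and of Schwann cells and nerve (adjusted p = 0.034 each) and of satellite cells (0.015). Of red blood cell markers 4 of 5 rose (2 under median centring), such as Alas2 (0.62) and Hba-a1 (0.61), with a median of 0.61 (adjusted p = 0.186). Of Schwann cell and nerve markers 3 of 6 rose (0 under median centring), such as S100b (0.41), with a median of 0.27 (adjusted p = 0.236), or 5 higher and 1 lower adjusted over the list alone, and 1 fell without transgenic array 3 or 7. Of 8 fibroblast markers the collagens Col1a1 (0.68) and Col1a2 (0.37) rose, with a median of 0.17 (adjusted p = 0.264). Brown adipocyte markers had 1 of 6 higher and 1 lower, with a median of 0.13 (adjusted p = 0.889). Of brown adipocyte markers 3 were higher without the array labelled wild type 4 and 0 without wild-type array 2, 3, 5 or 6 or transgenic array 2, 5 or 7. Endothelial markers had 1 of 8 lower, Kdr (-0.27 on its brightest probe and 0.29 on the other), with a median of 0.12 (adjusted p = 0.559), and 1 endothelial marker rose without wild-type array 1 or 6 or transgenic array 4 or 5 and 2 without transgenic array 2. Smooth muscle and pericyte markers had 1 of 7 higher, Cspg4 (0.29), and a median of 0.03 (adjusted p = 0.559). Macrophage markers had 1 of 7 lower, Csf1r (-0.25), and a median of -0.10 (adjusted p = 0.425). Without wild-type array 2, 2 macrophage markers were lower. Satellite cell markers had 1 of 5 lower, Chodl (-0.25, or -1.01 with Agilent's own log ratio), and a median of -0.09 (adjusted p = 0.425). Adjusted over the list alone the counts of these last 5 lists and of fibroblasts and red blood cells were equal to those over all genes. Lymphocyte markers had 3 measured members, with Cd4 at 0.24, and neutrophil markers 2, with S100a8 at 1.01 (2.86 with Agilent's own log ratio), too few for a set test. Without the array labelled wild type 4 or wild-type array 5, 1 neutrophil marker fell.

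Of the 25 gene lists, 15 passed the set test with the preset correlation and 2 with an estimated correlation. With the slide as a fixed block 15 lists passed, and without the array labelled wild type 4, 14. Of 145 named genes, 55 changed their call under median centring without loess and 46 with the adipocyte covariate.

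The number of members past the threshold also fell with the adipocyte covariate. Since a covariate that differs between the groups can widen the errors, a lower count does not by itself show smaller differences. The count was 5 higher for the other amino acid enzymes and 5 for slow-fibre genes, 7 lower for respiratory complex I and 7 for glycolysis and glycogen, 3 lower for ATP synthase and 3 for clock genes, and 1 higher and 2 lower for fatty acid and triglyceride synthesis. With the covariate 0 heat shock genes were lower, 0 insulin and growth signalling genes were higher, and 0 markers of fibroblasts and 0 of red blood cells were higher. Under median centring 0 markers passed for brown adipocytes, endothelial cells, smooth muscle and pericytes, macrophages, lymphocytes and satellite cells.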

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

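Of the tests in this part, the position of the array labelled wild type 4 between the groups, the fit with an adipocyte covariate and its look at risen genes alone were chosen only after the results they bear on had been seen. An array was singled out where its gap to the nearest other array of its group was large against the range of the group. Chance alone singles out about 1 in 20 groups, or 14.6 of the 292 groups of arrays looked at, and 15 were singled out, so single cases here can be chance. Values are the log2 ratio of the array minus the mean of the other arrays of its group.

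Ucp1 on the array labelled wild type 4 lay 4.04 above the mean of the 5 other wild-type arrays (0.45 against -3.58 ± 0.50, SD). The tables argue against a transgenic mouse under a wild-type label, since over the genes that differ between the groups this array lay at a median of 0.084 of the way from the other wild-type arrays to the transgenic mean, where the others lay at -0.09 to 0.04. They also argue against a faulty spot, since the spot carried 0 outlier flags and 4 of 5 brown adipocyte markers were highest on this array among the wild-type arrays. Brown fat in the sample stays open as a candidate explanation: Cidea lay 3.44 above the other wild-type arrays (1.80 against -1.64), second to Ucp1 among 17133 genes, but the median excess of the 5 markers was 0.29, with Prdm16 at 0.01. Apoc1 (1.11), Thrsp (1.00), Plin1 (0.90) and Adrb3 (0.89), members of the adipocyte lists used here, also read higher on this array than on all other arrays. Genes outside those lists, such as Gm13157 (1.47) and Hist1h4d (0.94), did so too. All of these were picked after their values were seen. By the limit set beforehand, a median under 0.3, brown fat would be excluded, and it was left open only after the value was seen, because 0.29 lies within the spread of the same median over the other wild-type arrays (SD 0.12) from that limit.

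Pck1, which adipocytes express strongly, also lay 1.73 above the other wild-type arrays on the array labelled wild type 4. Of 8 white adipocyte markers, 6 were highest on this array among the wild-type arrays, with a median excess of 0.69, and all 8 also rose in the transgenic group. A second list of adipocyte genes, fixed before its values were seen, had a median difference of 0.24 between the groups, with 8 of 19 genes higher and 1 lower, Ces1d, so that more fat tissue in the transgenic samples cannot be told apart from a change of the marker genes alone. More fat tissue as the cause of the rise of 3 lists (stress response regulators, serine and one-carbon enzymes, other amino acid enzymes) is argued against, since with the adipocyte covariate the median size of their 35 members past the threshold (30 higher, 5 lower) was 1.05 times its value without it (0.91 against 0.86). Of the 30 that rose alone the median was 1.12 against 0.89, and 23 still passed the limma threshold, while transporters and synthetases were not part of this test.

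On transgenic array 5, 6 genes were singled out. They were Myh7 (0.76), Pvalb (-0.69), Pgam2 (-0.37), Me1 (-0.29), Cspg4 (-0.33) and S100a8 (1.23). On other arrays they were Atf5 on transgenic array 2 (0.54), Igfn1 on transgenic array 1 (-0.21), Odf3l2 on wild-type array 2 (-0.54), Cox7a1 (-0.38) and Phkg1 (0.21) on wild-type array 3, Prdx5 on wild-type array 6 (0.21) and Hspb7 on wild-type array 1 (0.57).

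Chance can be excluded for the number of genes between the groups. The real division gave 5695 genes, and of 100 divisions of the 13 arrays into 7 and 6 only 1, the real one, gave as many. The highest other gave 4394, in a division whose group of 7 held 6 wild-type arrays and 1 transgenic array and so nearly repeats the real one in mirror image, and 97 divisions gave 0 genes by limma. For the number of gene lists the real value was 15 and the highest other also 15, and 3 of the 100 divisions gave as many, the real one included, so chance is excluded at a share under 0.05. The other divisions with 15 lists held 2 transgenic arrays in the group of 7, so they keep much of the real contrast in mirror image. Across all other divisions the median was 5 lists, with at least 1 list in 95 of them. Many of these also keep part of the real contrast, so that median is not a rate of calls by chance. Yet divisions with 4 transgenic arrays in the group of 7, close to balance, called up to 9 lists. A single list call with the preset correlation is therefore weak evidence that the list differs between the groups.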

How the results depend on the processing

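The fit with an adipocyte covariate and the one that keeps outlier spots were chosen after seeing the data. The number of genes was 5138 to 5703 when each array was left out in turn (2581 to 2933 higher and 2528 to 2770 lower). It was 3952 to 6597 in the other settings that count genes, except 3. With every probe on its own, 7222 of 22716 probes passed. Median centring without loess gave 1303 genes (1039 genes higher, 264 genes lower), of which 1302 are among the 5695. A log2 difference of at least 1 left 285 (137 higher, 148 lower), by its construction. With the adipocyte covariate 2482 genes passed (1250 genes higher, 1232 genes lower), and Ucp1 was 1.32 (adjusted p = 0.333). That covariate itself differs between the groups (-0.66 ± 0.29 in wild type and 0.27 ± 0.33 in transgenic samples, SD). Among the wild-type arrays it was highest on the array labelled wild type 4 (-0.20), where Ucp1 was highest too. The standard error of Ucp1 was 0.83 with the covariate against 0.50 without it. Otherwise Ucp1 was 2.97 to 3.91 with each array left out and 2.99 to 3.99 in the other settings, and Fgf21 was 3.93 to 4.15 and 3.95 to 4.88. The number of gene lists was 14 to 16 with each array left out, 2 with an estimated correlation, 18 with fry, and 11 to 18 in the other settings. Median centring ended the calls of complex I, ATP synthase and glycolysis and added those of mitochondrial biogenesis (0.045) and antioxidant genes (0.025). Of 145 named genes, 55 kept their call in every setting other than leaving out arrays in turn, 55 changed it with median centring, 46 with the covariate and 82 with the minimum difference of 1. With median centring Atp5k (0.11), Acadm (0.047) and Csf1r (0.0015) were above 0, but below the 0.14 by which that scaling moved the median of all genes, so relative to it they did not reverse. Reversed values were Ndufv3 (0.21, adjusted p = 0.0099) and Kdr (0.012) with the mean over a gene's probes, and Alas2 (-0.057) and Hba-a1 (-0.16) with the covariate. Adipoq (-0.16), being part of the covariate, is no test of it. Ndufv3 and Kdr have probes that differ in direction; for the other changes the cause was not tested.

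Tests of the lists with the slide as a random block, and with the minimum difference, were not run. The replicate numbers of the labels were not used as pairs in the main fit. Deviations of mice with the same number correlated at -0.23 to 0.23, over 0.1 in 3 of 6 numbers, and 1 wild-type array correlated best with its own number. Numbers 1, 3, 4 and 6, whose mice shared a slide, gave 0.07 to 0.23. Numbers 2 and 5, whose mice lay on different slides, gave -0.23 and -0.16. These correlations therefore cannot tell a pairing of mice from a shared slide. The replicate block gave 5369 genes, 15 lists, 3.31 for Ucp1 and 3.95 for Fgf21. Signal over background limits the probes measured: without the filter on dim probes 5473 genes passed, and with a filter on all 13 arrays 5278.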

Other observations

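The genes and probes of the first 2 paragraphs, and the tests on polyamine genes and on the genome window, were chosen after the results they bear on had been seen. Odz4, now named Tenm4 and coding for a teneurin, a cell surface protein, did not pass on its brightest probe (-0.17 ± 0.07, adjusted p = 0.128), which lies on chromosome 7 from 103358859 to 103358918 in mm9. Probes from 104057003 to 104057062 and from 104059544 to 104059603 were higher in the transgenic samples by 3.92 ± 0.10 and 3.70 ± 0.13 (limma on all probes without the filter, Benjamini-Hochberg adjusted p = 7.5e-17 and 8.2e-15). The remaining probe, from 104033939 to 104033998, read 0.20 and was well above background on 3 transgenic and 0 wild-type arrays. Phyhd1, a dioxygenase gene, was likewise missed on its brightest probe and higher by 2.37 on another. Together with 1 unnamed transcript on chromosome 16, 3 genes outside the 5695 had another probe that changed by at least 1. The exons these probes lie in were not analysed here.

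On chromosome 14, the files hold probes named after the region from 21029450 to 21049451, 253 kb from the probe of Zmynd17. Of the 5 probes of its F strand, as the files name it, the 4 well above background in both groups were higher in the transgenic samples, by 1.13 to 3.33, and Zmynd17 itself read -3.29. Whether this transcript and Zmynd17 are related was not tested.

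The rise of aminoacyl-tRNA synthetases did not extend, as a class, to the genes listed as mitochondrial enzymes. Their median difference was 0.064 over 15 genes, against 0.50 over the 20 cytosolic ones (permutation test of the class labels over genes, 100000 resamples, two-sided p = 0.0077), and 3 of the 15 passed, Ears2 (0.62), Tars2 (0.42) and Wars2 (0.28). A rise of all synthetases alike is argued against by this test. Genes are not independent replicates in it. The mitochondrial list held no glycine or lysine enzyme, and Gars and Kars were counted as cytosolic only.

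Amd2 and Smox were among the strongest decreases, and lower expression of polyamine genes as a class may be a candidate explanation. The other 11 polyamine genes had a median difference of 0.042, with Odc1 (-1.88), Sms (-1.17), Oaz1 (-0.32) and Oaz2 (-0.31) lower and the spermidine synthase Srm (0.63) higher, so that members moved both ways. By the limit first written for this test that median would exclude the explanation, and it was left open after the values were seen, because the members moved both ways. A region linked to the transgene might show as genes changed by at least 1 that gather near 1 place. The densest window of 10 Mb, on chromosome 11, held 9 such genes among 169 tested. The 95th percentile of 10000 random reassignments was 10 (permutation p = 0.257). No gathering was detected by this count. It used the brightest probe of each gene, so Odz4 and Phyhd1 entered as unchanged, and it could miss a region with few changed genes.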
